A study of Mus musculus with 3 samples.

How the data were processed

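The data were 3 RNA-sequencing libraries of splenic T lymphocytes of female BALB/c mice, 6 to 8 weeks old, isolated with CD90.2 magnetic beads, cultured in RPMI medium with 2% fetal bovine serum and treated with LZ-8 for 10 h, per the labels. RNA was extracted with Trizol, libraries were made with the Ion Proton RNA-Seq kit v2.0 and sequenced on an Ion PI chip, per the labels. How ribosomal RNA was removed, and whether the kit kept the strand in the counting, is not given in the sources used here.

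The authors deposited 1 table of raw counts per gene symbol, with a column per replicate named as the titles of the samples. The genome build was mm10, per the submitters' processing notes, and the aligner, the counting tool, the annotation and any filters are not given in the sources used here. The values were whole numbers with a different total in each column, and 44788 rows were present. Because the counting rule is not known, overlapping genes, antisense genes and near-identical copies are uncertain.

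All libraries carried the same label, so there was 1 group with 3 replicates and no comparison between groups. The design, gene lists, rule for named genes and alternatives were fixed before the data were examined, except the mitochondrial list and the alternatives that concern length and GC trends, which were set afterwards. Counts were scaled by the trimmed mean of M-values (TMM) with edgeR 4.0.16 in R 4.3.3, with factors of 0.962, 1.01 and 1.03, and are given as CPM of the effective library size. Levels are the mean and SD over 3 libraries. Ratios of 2 genes were taken as log2 ratios within each library, with a two-sided exact sign-flip test unable to go below 0.25 at this number of libraries.

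The biological coefficient of variation is the square root of edgeR's common dispersion with an intercept-only design over 13676 genes kept by its expression filter. Genes differing between replicates were found with a chi-square test of the 3 raw counts against the effective library sizes, for genes with an expected count of 5 or more in each library, at a Benjamini-Hochberg adjusted p of 0.05. Both steps were tested on simulated data. For the chi-square step, over 15394 genes, 24%, 54%, 80% and 100% of 50 genes each changed by 1.25-, 1.5-, 2- and 4-fold were recovered, with 3.73% false calls among the genes called. Simulated coefficients of variation of 0.05, 0.1 and 0.2 were estimated as 0.0506, 0.0992 and 0.199 over 13811, 13766 and 13714 genes.

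Gene lists covered T cell identity, Th17, Th1, Th2, regulatory and follicular helper T cells, Th17-inducing signalling, early activation, naive and quiescence genes, cytokines and chemokines, cytotoxic and gamma-delta T cells, interferon-stimulated genes, cell cycle, glycolysis, apoptosis and stress, and ribosomal and mitochondrial protein genes. Lists of other cells covered B cells, macrophages and monocytes, neutrophils, dendritic cells, NK cells, erythroid cells, platelets, and stroma and endothelium. Some genes stand in more than 1 list, such as Irf4 in the Th17 and early activation lists and Nkg7 in the cytotoxic and NK lists. Il2ra, Tnfrsf4 and Icos stand in the regulatory and early activation lists, and Eomes in the Th1 and NK lists. Mitochondrial genes were found by their chromosome, since their symbols in the table lack the usual prefix, and Ahsp of the erythroid list was not matched.

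The Th17 list was compared with 4 other T helper lists by a two-sided permutation test over genes on log2(mean CPM + 1), with 100000 resamples, shared members left out and Benjamini-Hochberg adjustment over 4 tests. The level of each list is the percentile of its median among 10000 random lists of the same size from all genes with a count. The shift of a list between libraries is the range of its median deviation, over members with a mean of at least 1 CPM, as a percentile among 10000 random lists matched on expression in 20 bins, with the 95th percentile as the limit. Other cell types were measured as summed CPM in percent of the T cell identity list.

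Named genes were genes fixed in advance (T helper regulators, cytokines and T cell surface or activation genes), the 10 with the highest mean CPM, and the 10 with the largest coefficient of variation among genes with a mean of at least 10 CPM that passed the chi-square test. They also included the 2 most abundant members of each list. Some genes that this rule names are not reported here. Coordinates, exon lengths and GC content came from GENCODE release M21 (GRCm38), where 32233 symbols matched, 30997 directly and 1236 through older names, covering 92.7% of the genes tested by chi-square. For the trend of each library with length and GC content, splines with 6 degrees of freedom were fitted robustly to genes of at least 5 CPM. Pseudogene rows were aligned to coding transcripts with blastn 2.17.0.

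Alternatives were DESeq2 1.42.0 size factors and dispersion, no scaling factor, other detection limits, filters, thresholds and pseudocounts, CPM per kilobase of exon, another background for random lists, and leaving out each replicate. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6 was used. Counts per library ranged from 13239482 to 15683820, and a share of counts is given with its exact (Clopper-Pearson) 95% binomial interval. No effect of LZ-8 was estimated, since untreated cells were not analysed here.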

Results

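Splenic T cells held with LZ-8 for 10 h carried abundant transcripts of activated T cells. Cd69, an early activation receptor, was at 549 ± 29.6 CPM (counts scaled to a common library size), and Il2ra, the inducible chain of the interleukin-2 receptor, at 828 ± 73.6 CPM (mean ± SD here and below, n = 3 libraries). Among the regulators of T helper fates, Foxp3, the regulator of regulatory T cells, was at 217 ± 1.45 CPM and Tbx21, the regulator of Th1 cells, at 61.4 ± 1.71 CPM. Il17a was at 5.83 ± 1.17 CPM, below Ifng at 42.2 ± 5.71 CPM. Cd8a was at 134 ± 15.3 CPM, so the isolated cells were not helper T cells alone. The levels are those of the whole pool and do not measure a balance among helper cells. All 3 libraries were from treated cells, so these are levels in treated cells and no effect of LZ-8 was measured.

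Messenger RNA was profiled in T lymphocytes isolated from spleens of female BALB/c mice with beads against CD90.2, a surface protein of mouse T cells. LZ-8 is an immunomodulatory protein of the fungus Ganoderma lucidum. The labels put the 3 libraries in 1 group, and the title of the series names the differentiation of Th17 cells as its subject. The libraries held 13239482, 15007652 and 15683820 counts for replicates 1, 2 and 3, over 44788 gene symbols. A level of 3 counts, used as the detection floor, corresponded to 0.236, 0.198 and 0.186 CPM, and floors and intervals cover counting error only. In every library 12941 genes reached 1 CPM. The labels do not say whether the replicates came from separate animals or cultures. SDs and chi-square p-values therefore concern only the spread between these samples, which may be technical. The p-values of the permutation test were taken over genes and do not measure that spread.

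The regulators of T helper fates spanned a wide range of levels. Bcl6, the regulator of follicular helper cells, was at 39.7 ± 2.67 CPM and Gata3, the regulator of Th2 cells, at 36.0 ± 4.76 CPM, both below Tbx21 and Foxp3 in each of the 3 libraries. CPM is not divided by transcript length, so the exonic length of a gene enters any comparison of levels between genes. Foxp3 lies on chromosome X from 7573644 to 7595245 and Tbx21 on chromosome 11 from 97098071 to 97115331 (GRCm38, whole gene bounds of the GENCODE annotation). Gata3 lies on chromosome 2 from 9857078 to 9890034, and Bcl6 on chromosome 16 from 23965052 to 23988852.

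The cytokines of Th17 cells were detected at low levels in every library. Il17a had 88, 91 and 74 counts in replicates 1, 2 and 3, and Il17f 61, 63 and 51 counts, with a mean of 4.04 ± 0.823 CPM. The genes are neighbours on chromosome 1, Il17a from 20730905 to 20734496 and Il17f from 20777146 to 20790617. Il17a was 7.29-fold lower than Ifng, with a log2 ratio of -2.87 ± 0.11, and 6.88-fold lower than Il2, the growth factor made by activated T cells, which was at 39.7 ± 3.03 CPM. Both ratios had the same sign in all 3 libraries and exceeded their SD, although 3 values cannot give a two-sided p below 0.25 in an exact sign-flip test. Il4, the cytokine of Th2 cells, was at 2.87 ± 0.796 CPM, and the log2 ratio of Il17a to Il4 was 1.05 ± 0.71, ranging from 0.40 to 1.82 between libraries. Ifng lies on chromosome 10 from 118441046 to 118445892 and Il4 on chromosome 11 from 53602982 to 53618669.

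**Figure D1:**
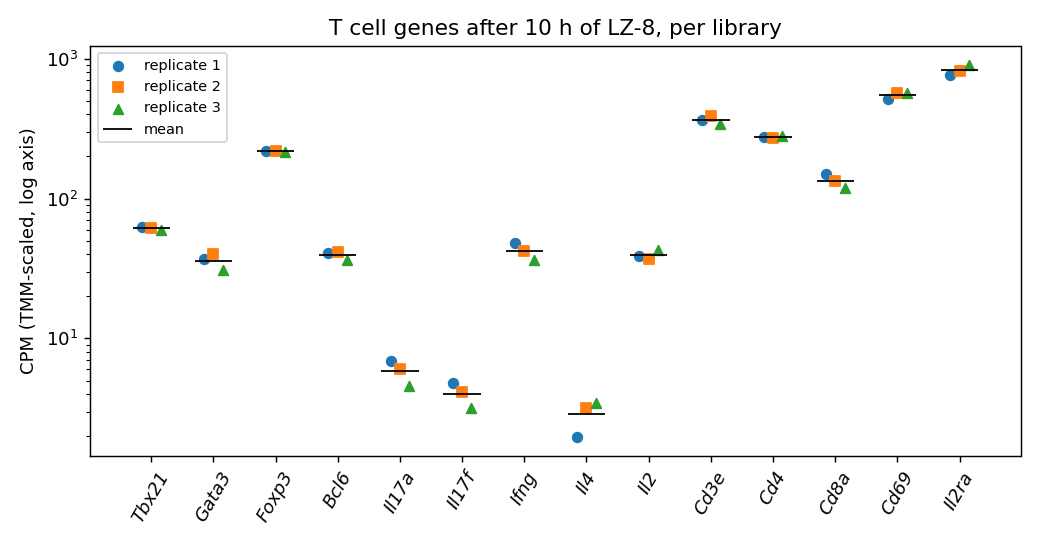
Levels of the T helper regulators, cytokines and T cell surface genes in the 3 libraries, in TMM-scaled CPM on a log axis, with points for libraries and a line for the mean. Il17a lies at 5.83 CPM on average, below Ifng at 42.2 CPM and Il2 at 39.7 CPM and below both in each library.

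Lists of genes typical of each T helper fate were then set against the Th17 list. Of the 18 Th17 genes, 9 had a mean of at least 10 CPM and none was below 1 CPM in every library. The most abundant were Irf4, a transcription factor also induced in other activated lymphocytes, at 2409 ± 212 CPM, and Hif1a, the oxygen-sensing factor, at 438 ± 49.4 CPM. The mean log2 level of the Th17 list was lower than that of the regulatory T cell list by -1.58 (SD between libraries 0.02). This had an unadjusted p of 0.0989 and an adjusted p of 0.396 in a two-sided permutation test over genes. Differences from the Th1 list (-0.49), the Th2 list (0.79) and the follicular helper list (-0.41) each had an adjusted p of 0.698 in the permutation test, so none of the 4 comparisons passed. Genes are not independent replicates, and the lists were measured over all isolated cells and not over helper cells alone. With members of at least 1 CPM alone, the Th17 to Th2 difference turned to -0.26 (adjusted p = 0.81 in the permutation test, with a range of 0.570 to 0.893 over the alternatives).

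The other T helper lists were led by signalling genes and surface receptors. In the Th1 list, 10 of 14 genes had a mean of at least 10 CPM, among them Stat4 at 99.5 ± 3.74 CPM. In the Th2 list, 6 of 13 genes reached that level, led by Stat6 at 447 ± 10.5 CPM and Il4ra at 285 ± 28.7 CPM, and 3 were under 1 CPM in every library. In the regulatory T cell list, 11 of 14 did, led by Il2ra and by Tnfrsf4, the costimulatory receptor OX40, at 320 ± 37.1 CPM. In the follicular helper list, 8 of 11 did, led by the costimulatory receptor Icos at 209 ± 20.9 CPM and the inhibitory receptor Btla at 132 ± 19.8 CPM. Medians of these lists lay at the 84.1 (Th17), 97.3 (Th1), 62.4 (Th2), 99.97 (regulatory) and 97.8 (follicular helper) percentiles of random lists of the same size from all genes with a count. Against random lists from genes of at least 1 CPM the Th17 percentile was 6.34 and the Th2 percentile 1.40. Il2ra, Tnfrsf4 and Icos of the regulatory list also stand in the early activation list. The level of the regulatory list therefore need not come from regulatory T cells alone. In the list of receptors and transducers that act upstream of the Th17 fate, 11 of 13 genes had a mean of at least 10 CPM, led by Jak2 at 451 ± 39.4 CPM and Jak1 at 440 ± 22.8 CPM.

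T cell identity genes were abundant, with all 20 at a mean of 10 CPM or more and 18 at 100 CPM or more. Cd6 was at 887 ± 45.4 CPM and Cd3e, a chain of the receptor complex, at 364 ± 24.2 CPM. Cd4 was at 277 ± 4.73 CPM and Cd8a at 134 ± 15.3 CPM, a 2.08-fold difference (log2 ratio 1.05 ± 0.18). All 24 early activation genes had a mean of at least 10 CPM, and 15 had at least 100 CPM. Naive and quiescence genes were present alongside them, with 14 of 14 at 10 CPM or more, among them the lymph node homing receptor Ccr7 at 1348 ± 161 CPM and Satb1 at 1210 ± 68.7 CPM. Medians of the identity, early activation and naive lists lay at the 100, 100 and 99.98 percentiles of random lists.

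Glycolysis and stress genes were also high. In the glycolysis list, 15 of 16 genes had a mean of at least 10 CPM, with Ldha at 1209 ± 29.4 CPM and Aldoa at 1131 ± 129 CPM. In the list of apoptosis and stress genes, 16 of 20 did, led by the endoplasmic reticulum chaperone Hspa5 at 989 ± 75.6 CPM and the stress response factor Atf4 at 565 ± 13 CPM. Both lists had medians at the 100 percentile. Cell cycle genes were at the 72.3 percentile, with 10 of 21 at 10 CPM or more. Their most abundant members were the replication licensing genes Mcm2 at 224 ± 7.25 CPM and Mcm5 at 203 ± 4.41 CPM. The interferon-stimulated list lay at the 94.8 percentile, with 14 of 20 members at 10 CPM or more, among them Gbp4 at 367 ± 14.1 CPM. Against random lists from genes of at least 1 CPM, the cell cycle percentile was 0.66 and the interferon-stimulated percentile 26.9, and per kilobase of exon the cell cycle percentile was 33.4.

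In the list of 28 cytokines and chemokines, 11 had a mean of at least 10 CPM, 4 were under 1 CPM in every library, and the median lay at the 74.6 percentile. Tgfb1 at 184 ± 13.5 CPM and Ccl4 at 120 ± 8.19 CPM were the most abundant. Cytotoxic lymphocyte genes were at the 77.1 percentile, led by Nkg7 at 51.0 ± 1.36 CPM and Cst7 at 48.3 ± 1.82 CPM, with 1 of 10 members under 1 CPM in every library. Against random lists from genes of at least 1 CPM, the cytokine and cytotoxic percentiles were 0.16 and 10.6. Gamma-delta T cell genes were at the 20.9 percentile, with 5 of 9 under 1 CPM in every library. The constant gene of the delta chain, Trdc, was at 2.25 ± 0.324 CPM and 5830411N06Rik at 1.64 ± 0.431 CPM. The gamma-delta percentile was 4.72 per kilobase of exon and 0 against genes of at least 1 CPM.

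**Figure D2:**
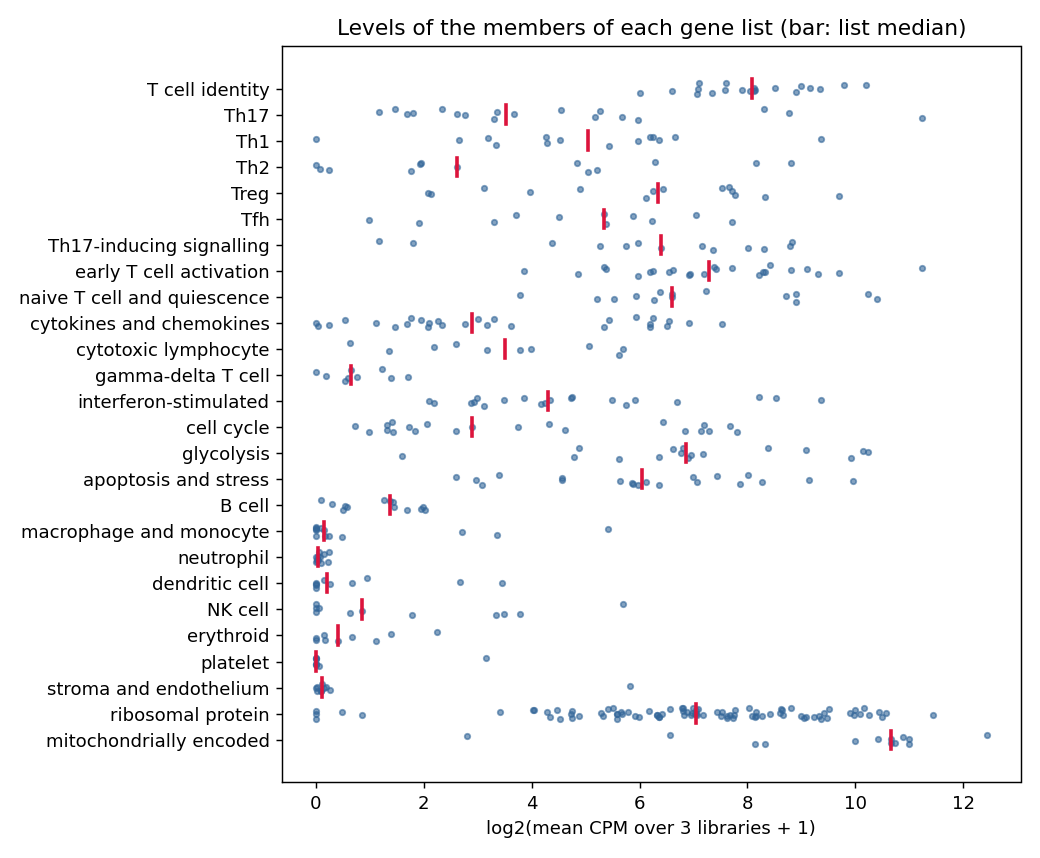
Mean levels of the members of each gene list as log2(mean CPM + 1) over 3 libraries, with points for genes and a red bar for the list median. Early activation genes have a median of 156 CPM, against 10.6 CPM for the Th17 list and 1.61 CPM for the B cell list.

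Markers of other spleen cells were scarce. Summed CPM of all non-T lists came to 3.58 ± 0.00790% of the summed CPM of the T cell identity list. Per kilobase of exon the share was 6.57%, and as a mean over members it was 0.833%. Pecam1 and Nkg7 made up 42.1% of the summed CPM of all non-T lists. From replicate 1 to replicate 3 the macrophage share fell from 0.855% to 0.730% and the stroma share rose from 0.785% to 0.888%. The small SD of the sum therefore does not mean that each part was constant. B cell markers made up 0.272 ± 0.00817%, with Pax5 at 2.96 ± 0.228 CPM. NK cell markers made up 1.23 ± 0.0241%, but 58.7% of that was Nkg7, which cytotoxic T cells also express, and Prf1 was at 12.7 ± 1.16 CPM. The macrophage and monocyte list (0.811 ± 0.0703%) was 72.8% Hmox1, which T cells also express, at 41.8 ± 7.12 CPM, followed by Mpeg1 at 9.20 ± 1.44 CPM. Dendritic cell markers made up 0.242 ± 0.0253%, with Zbtb46 at 9.90 ± 0.888 CPM and Ccr9 at 5.39 ± 0.642 CPM. The stroma and endothelium list (0.799 ± 0.0823%) was 98.7% Pecam1, at 55.9 ± 5.76 CPM, and Sparc was at 0.205 ± 0.300 CPM. Platelet markers (0.112 ± 0.0116%) were 99.4% Itga2b, at 7.90 ± 0.705 CPM, while Gp1ba had 1, 1 and 0 counts. Erythroid markers made up 0.109 ± 0.0201%, with Car2 at 3.74 ± 0.50 CPM and the haemoglobin gene Hba-a1, whose reads can be shared with its near-identical copy, at 1.64 ± 0.192 CPM. Neutrophil markers made up 0.0102 ± 0.00831%, with 6, 1 and 0 counts for Ngp and 4, 3 and 0 for S100a9, and 0.00554% without replicate 1. Members under 1 CPM in every library numbered 5 of 13 in the B cell list, 10 of 13 in the macrophage list, 12 of 12 in the neutrophil list and 7 of 10 in the dendritic cell list. They numbered 6 of 11 in the NK list, 6 of 9 measured in the erythroid list, 7 of 8 in the platelet list and 9 of 10 in the stroma list. List medians lay at the 36.1 (B cell), 1.01 (macrophage), 0 (neutrophil), 2.86 (dendritic), 24.0 (NK), 12.4 (erythroid), 0 (platelet) and 0.53 (stroma) percentiles of random lists. Per kilobase of exon, the B cell list was at the 6.12 percentile, the macrophage list at 0.04, the dendritic list at 0.20 and the NK list at 13.8, and all 8 lists were at 0 against genes of at least 1 CPM. Without replicate 1, 2 or 3, the macrophage percentile was 0.30, 1.78 and 0.94, the dendritic percentile 4.44, 2.62 and 1.55, and the stroma percentile 0.195, 0.93 and 0.09. Per kilobase, the shares were 3.55% for NK, 1.63% for macrophage, 0.482% for stroma, 0.350% for erythroid, 0.113% for dendritic and 0.0390% for neutrophil markers. As a mean over members, they were 2.23% for NK, 1.60% for stroma, 1.247% for macrophage, 0.484% for dendritic, 0.418% for B cell, 0.281% for platelet, 0.241% for erythroid and 0.0170% for neutrophil markers.

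The 10 most abundant rows were led by a copy of the 18S ribosomal RNA, Rn18s-rs5, on chromosome 17 from 39846958 to 39848788. It took 5.83% of counts in replicate 1 (exact 95% interval 5.81% to 5.84%), 2.37% in replicate 2 (2.36% to 2.38%) and 0.992% in replicate 3 (0.987% to 0.997%). Translation genes followed, with Eef1a1 at 7371 ± 602 CPM, Eef2 at 4191 ± 282 CPM, Rpl4 at 2766 ± 148 CPM and the nucleolar protein gene Ncl at 2319 ± 249 CPM. The chaperone gene Hsp90ab1 was at 6600 ± 532 CPM, the mitochondrial COX1 at 5549 ± 430 CPM, and Irf4 completed the protein-coding genes of this set with Lars2. Lars2 had 7328, 4119 and 2280 CPM in replicates 1, 2 and 3, falling in the same order as the share of Rn18s-rs5. Whether the reads of Lars2 came from its messenger RNA or from other RNA was not tested, so its level is uncertain. The pseudogene Gm13456 was at 3832 ± 588 CPM. Rows with near-identical copies elsewhere in the genome, here Rn18s-rs5, Gm13456, Eef1a1 and COX1, are uncertain because the counting could split or share their reads. In the ribosomal protein list, 83 of 89 genes had a mean of at least 10 CPM and 5 were under 1 CPM in every library, and Rpl8 followed Rpl4 at 1523 ± 319 CPM. All 13 mitochondrially encoded protein genes were at 1 CPM or more in at least 1 library, with ND1 at 2048 ± 179 CPM. Both lists had medians at the 100 percentile.

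The replicates differed by more than counting noise, with replicates 1 and 3, which had the highest and lowest 18S shares, the furthest apart. The chi-square test, adjusted by the Benjamini-Hochberg method, found 6589 of 15392 tested genes (42.8%) to differ between the 3 libraries, a test of libraries and not of conditions. Of these, 2130 differed by 1.5-fold or more and 1087 by 2-fold or more. Among the 2130, replicate 1 was highest for 1400 and replicate 3 lowest for 1440. The median coefficient of variation was 8.67% over 9204 genes with a mean of at least 10 CPM, and the biological coefficient of variation from edgeR was 0.153. Pearson correlations across genes, which are not independent replicates, were 0.991 for replicates 1 and 2, 0.979 for 1 and 3, and 0.992 for 2 and 3. No pair agreed within sampling noise, so no library was taken for a copy of another. Leaving out replicate 1 or replicate 3 lowered the count of differing genes to 3836 and 3555.

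The genes that varied most between libraries were mostly small non-coding RNAs, each of the 10 with its highest CPM in replicate 1. Rmrp, the RNA of RNase MRP, had 32.4, 9.76 and 2.54 CPM in replicates 1, 2 and 3. The U2 spliceosomal RNA gene Rnu2-10 had 32.7, 7.25 and 4.34 CPM, and the 7SL RNA gene Rn7s2, which encodes the RNA of the signal recognition particle, had 303, 96.5 and 35.6 CPM. The 4 copies of the U3 nucleolar RNA, Rnu3b1 to Rnu3b4, had 67.1 to 72.4 CPM in replicate 1 and 7.62 to 7.87 CPM in replicate 3, and their near-identical sequences leave each copy uncertain. Mir6236 had 733, 233 and 79.5 CPM, and the pseudogene Rpl17-ps7 had 31.3, 10.6 and 3.96 CPM. The row LOC101055851 had 694 counts in replicate 1 and 0 in the others, at least 276-fold higher than the floor of 3 counts in replicate 2 and at least 293-fold higher than that in replicate 3.

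Coding genes followed a trend with transcript length and base composition. The 900 coding genes with the least exonic sequence had a median log2 ratio of replicate 1 to replicate 3 of 0.27, and the 900 with the most had -0.19. The 900 with the lowest GC content had -0.27 and the 898 with the highest 0.09. As a group, ribosomal protein genes were highest in replicate 1, with a range of 0.64 (log2) between library medians, at the 100 percentile of 10000 random lists matched on expression. Of the 85 members tested, 82 differed over all genes tested and 83 when adjusted over the list alone. Interferon-stimulated genes were highest in replicate 3, with a range of 0.33 at the 99.97 percentile of matched lists, and 14 of 20 members differed (15 when adjusted over the list alone). Gbp4 had 353, 367 and 381 CPM in replicates 1, 2 and 3. Mitochondrial genes had a range of 0.33 (99.9 percentile, 13 of 13 differing, also when adjusted over the list alone) and cytokines and chemokines a range of 0.21 (98.9 percentile, 11 of 25 differing, 11 when adjusted over the list alone). With the length and GC trends removed, the interferon-stimulated list was at the 99.94 percentile and the ribosomal list at 100, while the cytokine list was at 63.0 and the Th2 list, before at 78.4, at 97.4. The early activation list had a range of 0.02 (7.18 percentile), and the lists of Th17 (57.1) and B cell genes (4.37) were also under the 95th percentile.

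**Figure D3:**
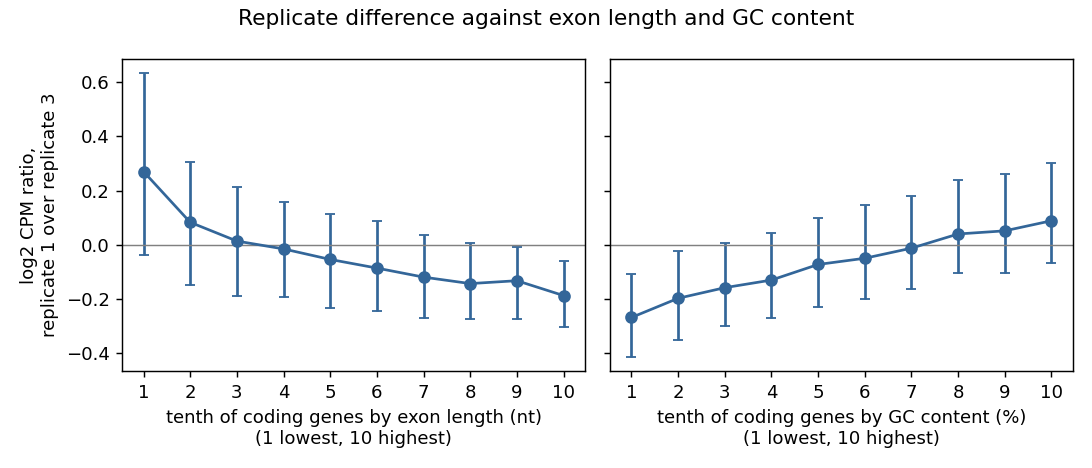
Median log2 ratio of CPM in replicate 1 over replicate 3 for coding genes of at least 5 CPM, split into 10 equal parts by exon length (left) and by GC content (right), with bars from the lower to the upper quartile of genes. The ratio goes from 0.27 in the shortest part to -0.19 in the longest.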

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

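The removal of length and GC trends was chosen only after the data were seen. Under the other scalings, filters and thresholds, the number of detected genes ranged from 12941 to 14049, and the Th17 list stayed below the regulatory T cell list, with differences from -1.74 to -1.57. The number of lists that shifted between libraries was 4, and 3 without replicate 2. With the trends removed it was also 3, over a different set of lists, since mitochondrial genes had no length or GC value and could not be tested, the cytokine list left and the Th2 list entered. Without 1 replicate in turn, the biological coefficient of variation ranged from 0.112 to 0.210, the latter without replicate 2, and the count of differing genes ranged from 3555 to 6403, also highest without replicate 2. Fewer libraries enter those tests. With the trends removed, the coefficient was 0.122, against 0.149 for the same genes before, and 5360 of 14241 genes differed against 6294 before, of which 4483 were shared.

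The difference between the Th17 and Th2 lists turned to -0.26 with members of at least 1 CPM alone, because that filter drops the lowest Th2 members. With genes of at least 1 CPM as background, the list percentiles were 6.34 for Th17, 63.9 for Th1, 1.40 for Th2, 98.96 for regulatory and 75.9 for follicular helper genes. That background leaves out genes that have a count but are under 1 CPM. Per kilobase of exon they were 46.7, 98.6, 45.6, 100 and 82.9 in the same order. Per kilobase, the log2 ratio of Il17a to Ifng was -2.72, by the construction of that scale. The share of other cells was 6.57% per kilobase and 0.833% as a mean over members. Among the remaining values, those of single genes, the Cd4 to Cd8a ratio, the other lists and the shares of single cell types, 170 moved by less than their SD and 67 by more. The mitochondrial list has no value per kilobase, since its genes had no length. Depth limits genes with few counts, such as Il4 with 25 in replicate 1.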

Other observations

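The tests in this part were chosen after the patterns were seen, except the alignment of pseudogenes, and the genes of the first 2 paragraphs were chosen after their values were seen. The NF-kB subunit gene Nfkb1 was at 1360 ± 16 CPM, Nfkb2 at 551 ± 7.87 CPM, Relb at 183 ± 9.82 CPM and Rel at 101 ± 10.5 CPM. Cd274, the ligand of the inhibitory receptor PD-1, was at 204 ± 16.4 CPM. Myc was at 635 ± 23.8 CPM, the amino acid transporter Slc7a5 at 633 ± 20.2 CPM, the transferrin receptor Tfrc at 484 ± 66.1 CPM and the G1 cyclin Ccnd2 at 1009 ± 42.1 CPM. In the cell cycle list, the replication gene Pcna was at 156 ± 4.31 CPM and Mcm3 at 140 ± 17.9 CPM, while the mitotic genes named here were lower, at 1.71 ± 0.114 CPM for Ccnb1, 2.31 ± 0.403 CPM for Cdk1, 2.60 ± 0.222 CPM for Plk1 and 1.48 ± 0.160 CPM for Aurkb.

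Of 35 T cell receptor beta variable rows, 16 were at 1 CPM or more in every library. Trbv13-1 took 23.8 ± 0.623% of their summed CPM, Trbv13-2 15.3 ± 0.728%, Trbv1 10.5 ± 0.377% and Trbv5 8.80 ± 0.662%. Related segments may share reads, and the identity between them was not measured. Of 12 Toll-like receptor rows, 4 were at 1 CPM or more in every library and 5 were below it in every library. Tlr1 was at 33.7 ± 3.02 CPM and Tlr4, with 10, 18 and 19 counts, at 1.05 ± 0.229 CPM.

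The 18S row Rn18s-rs5 was higher in replicate 1 than in replicate 3 by a log2 ratio of 2.65. Transcript length alone was argued against, because the central 95% of 723 coding genes with 1500 to 2200 nt of exon spanned -0.67 to 1.04. Histone rows (all symbols that start with Hist1h or Hist2h), whose mRNAs mostly lack a poly(A) tail, summed to 413, 287 and 162 counts over 66 rows in replicates 1, 2 and 3. Their log2 ratio between replicates 1 and 3 was 1.69 (95% interval 1.43 to 1.96, counting error only). The median was 0.62 for 79 coding genes of 300 to 800 nt. A candidate explanation is that more RNA without a poly(A) tail was carried into the library of replicate 1. The comparison cannot decide this, because the histone sum was set against the median of those coding genes and not their spread. It also assumes selection by poly(A) tail, and how ribosomal RNA was removed is not given in the sources used here. No biological explanation was tested, since the design holds 1 group, and a difference in histone expression between the replicates stays open.

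Interferon-stimulated genes were higher in replicate 3 than in replicate 1, with 17 of 20 members highest in replicate 3. Length and GC trends as the whole cause were argued against, because the list's range stayed at the 99.94 percentile of matched lists after their removal. RNA from B cells was argued against, because the summed B cell markers had a log2 ratio of replicate 3 to 1 of -0.00019 (95% interval -0.24 to 0.24), below the 0.33 of the list. RNA from myeloid cells, which the CD90.2 bead isolation would remove, stays open: macrophage and dendritic cell markers without Hmox1, mostly Mpeg1, Zbtb46 and Ccr9, had a log2 ratio of 0.27 (0.08 to 0.47), also 0.27 (0.06 to 0.48) without Ccr9, which T cells express too, although the macrophage gene Lyz2 had 2, 1 and 5 counts. No biological explanation was tested, and different interferon exposure of the replicates may also account for it.

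Pseudogene rows held 10.6%, 9.88% and 9.22% of counts in replicates 1, 2 and 3 (Rn18s-rs5 left out). Of 205 such rows with a mean of at least 100 CPM, 204 matched a coding transcript, with a median identity of 99.2% to the closest, against 89.8% for the 3564 rows under 1 CPM with a match, and 112 of the 204 were above that coding gene. The closest coding transcript need not be the source of a row. Gm13456 was set against Eef1a1-ps1, at 242 CPM, while Eef1a1 was at 7371 CPM. Gm13394, 99.9% identical to Gapdh, was at 232 ± 34.4 CPM, while the glycolytic gene Gapdh itself was at 28.2 ± 1.61 CPM. Reads of coding transcripts that were counted at near-identical copies are a candidate explanation, so the levels of genes with many copies, Gapdh among them, may be too low here. Transcription of the pseudogenes themselves was not separated from this.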
